A study of Drosophila melanogaster with 103 samples.

How the data were processed

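The series measured ChIP-seq in 3 Drosophila melanogaster cell lines: 41 libraries from D17, 41 from S2 and 21 from Kc167, with 2 replicates per antibody and 1 input per line. Per the submitters' processing notes, the authors trimmed reads with Trim Galore 0.6.4, aligned them with Bowtie2 2.3.5.1 to BDGP6 (dm6), handled alignments with SAMtools 1.13 and bedtools 2.29.2, and called peaks with MACS2 2.2.6. The deposited files are 50 peak lists, 1 per antibody and line, of which 39 are in the narrow layout (203005 peaks) and 11 in the broad layout (24649 peaks, none under 1000 bp). How the replicates and the input entered each list is not stated, and no file used here holds values per replicate or library, so the depth per sample is unknown and no test between lines or replicates was made.

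Each deposited peak has 3 values from the authors' peak caller: a score, a fold enrichment (a ratio), and a significance as -log10 q, the negative log10 of a corrected p-value. The score equalled 10 times the deposited -log10 q, within a tolerance of 1, for all 227654 peaks. The lowest deposited fold was 1.5 and the lowest -log10 q was 1.397. Peak names end in numbers in genome order. Of the numbers of a list, 0.968% to 8.63% are missing, so peaks may have been removed after calling. Where a number is skipped, a stretch between neighbouring peaks may have held a peak. Scores were used only to select the higher-scoring 50% or an equal number of peaks, and folds to describe, rank or filter peaks within a list. Folds were also compared between lines in the tests of explanations in the closing section.

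Genes came from a table of the Release 6 plus ISO1 MT assembly with 13935 protein-coding genes on the chromosomes used. The table gives no strand, so an H3K27ac peak was sought within 500 bp of either end of a gene in place of its annotated start. No genome sequence was used here, so the search for factor motifs was not run.

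The choices in this paragraph were made before the data were examined, except for the use of both gene ends. Overlap meant at least 1 bp. Overlaps of lists were compared with 1000 random placements that kept the width and chromosome of each peak, one-sided between lines and between antibodies and two-sided for marks, Trithorax, Engrailed and Rad21, with Benjamini-Hochberg adjustment over each family and a threshold of 0.05; the smallest p the placements can give is 0.001 one-sided and 0.002 two-sided. PcG sites were Ph peaks overlapped by a Pc, a Psc and a Pho peak of the same line, merged within 1 kb, and each was put in 1 of 4 states by the H3K27me3 and H3K27ac peaks over it. Shares have exact (Clopper-Pearson) 95% binomial intervals. A gene counted as covered when at least 50% of its body lay under H3K27me3. Gene lists (homeotic, segmentation, appendage, eye and head, neural and muscle, blood cell, PcG and trithorax, housekeeping) were compared with 10000 random lists of the same size, each member drawn from the 201 genes nearest in length. Symbols were matched through the table's symbols and synonyms; Dichaete and calypso found no match, D standing for the first, and names of the same gene were counted once. The named genes were all members of the homeotic, segmentation and appendage lists whose coverage differed between lines, up to 30 per pair of lines, and, for each ordered pair, the 5 genes with the longest covered body among those with 0 bp in the other line, 1 per peak. The named sites were the 3 PcG sites per line with peaks in the most lists.

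Alternatives tried were overlap over 50% of the peak width, the higher-scoring 50% of each list, equal list lengths, rotation of whole lists, a background of merged regions, other definitions of PcG sites, states, coverage and flanks, unmatched random lists and, chosen after seeing the data, leaving out stretches at skipped peak numbers, leaving out X and Y, shortening the Ph, Pc, Psc and Pho lists alone, and a peak over either gene end. Planted signals were tested on simulated data: 600 of 600 planted overlaps among 2984 simulated peaks and 300 of 300 planted PcG sites were found, and 9 of 200 null placements had a p under 0.05. The ratios of X to autosome folds, also chosen after seeing the data over all lists, have 95% intervals from 1000 draws of peaks with replacement. Overlap counts equalled those of bedtools in 78 of 78 comparisons at 1 bp and at 50% of the width. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1. Sequencing reads, expression data and accessibility data were not used here.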

Results

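Chromatin immunoprecipitation followed by sequencing was profiled in 103 libraries from 3 cultured lines of Drosophila melanogaster. D17 (ML-DmD17-c3, a line derived from imaginal disc tissue) gave 41 libraries, S2 (S2-DRSC, an embryonic line with blood cell features) gave 41, and Kc167 (another embryonic line) gave 21. There were 2 replicate libraries for each antibody and line, fixed from different flasks, and 1 input library per line. Of the 21 antibodies, 20 were used in D17, 20 in S2 and 10 in Kc167. They recognised Polycomb group (PcG) proteins, which keep developmental genes silent, proteins of the opposing trithorax group, DNA-binding factors that recruit them, the cohesin subunit Rad21, and histone marks. The PcG set held Pc, Ph and Psc of PRC1, E(z) and Pcl of PRC2, Pho and Sfmbt of the Pho-repressive complex, and Scm. H3K27me3 is the mark set by PRC2 and H2AK118ub1 the mark set by PRC1, while H3K27ac, H3K4me2, H3K4me3, H3K36me2 and H3K36me3 accompany active genes.

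The values came as 50 peak lists, 1 per antibody and line, with 227654 peaks in genome build dm6. D17 had 81372 peaks, Kc167 53028 and S2 93254. No list carried replicate values, so no spread between replicates can be set against a difference between lines, and the depth of the libraries is unknown. Fold enrichments are the authors' values and serve here to describe or rank peaks within a list. In the closing section they are also compared between lines. The exact 95% binomial intervals given with shares cover counting error only. List lengths differed widely for the same antibody: Pcl had 4065 peaks in D17 and 15159 in S2, Pc had 2529 in D17, 6298 in Kc167 and 2387 in S2, and the H3K4me3 lists held 5097 and 5069 peaks in D17 and S2.

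The lists of one antibody were first compared between lines. The D17 and S2 lists shared 75.5% of their combined length for H3K4me3, 67.8% for H3K36me3 and 64.9% for GAF, the factor that binds GA-rich repeats. Not every mark of active genes was as alike, with 48.3% for H3K27ac, 48.4% for H3K4me2 and 27.9% for H3K36me2. The Kc167 and S2 lists of H3K36me3 shared 77.7%. H3K27me3 lists shared 34.0% for D17 and S2, 27.3% for D17 and Kc167 and 38.6% for Kc167 and S2. Among PcG proteins, Pc lists shared 49.1% between D17 and S2 and Ph lists 44.3%, while Pcl lists shared 12.3%. The lists from the antibody to the C-terminal part of Trithorax (TrxC) shared 12.4% between D17, where they covered 9.54 Mb, and S2, where they covered 1.75 Mb; 1958 of the 2719 S2 peaks overlapped a D17 peak. The lists from the N-terminal antibody (TrxN), of 1.75 Mb and 3.01 Mb, shared 49.5%.

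**Figure D1:**
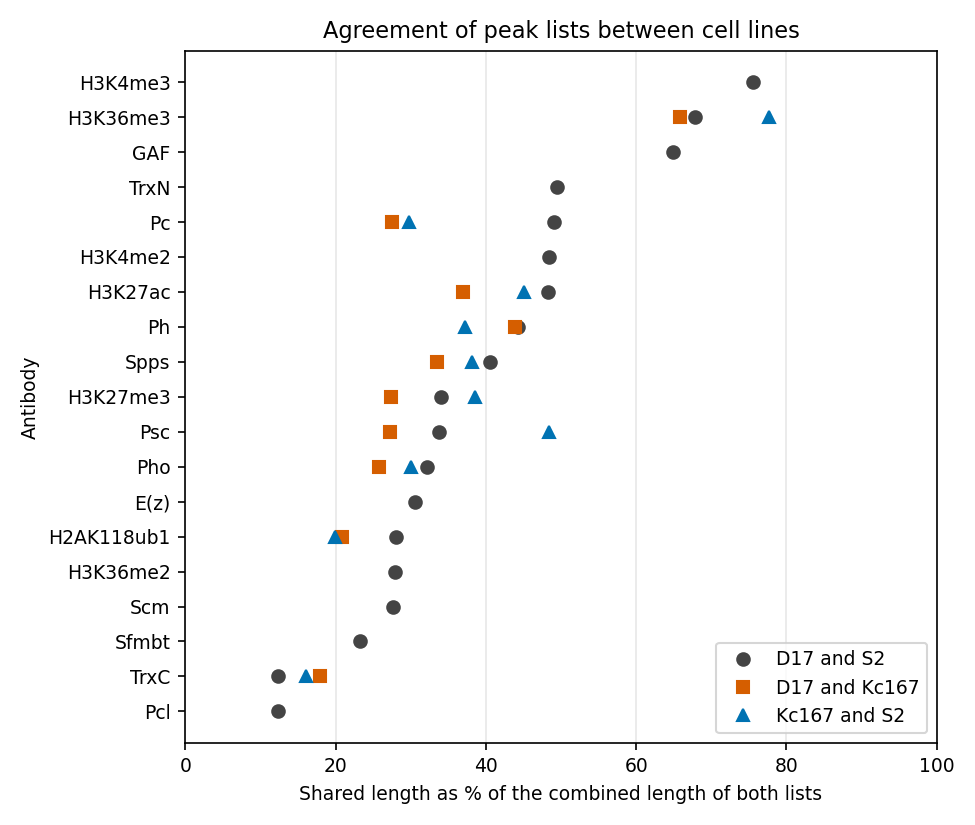
Shared length as a percent of the combined length of both lists (x axis) for each antibody (y axis), with 1 point per pair of lines. H3K4me3 (75.5%) and H3K36me3 (67.8%) lie highest for D17 and S2, and Pcl (12.3%) lies lowest.

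Counted by peaks, 92.9% of the 2773 D17 TrxN peaks overlapped an S2 TrxN peak by at least 1 bp, as did 89.5% of D17 H3K4me3 peaks and 71.7% of D17 Ph peaks. S2 peaks of Spps, a zinc finger protein found at PcG response elements, overlapped a Kc167 Spps peak in 88.5% of cases. Each of the 78 ordered comparisons lay above the mean of 1000 random placements of the list. The one-sided p was 0.001, the smallest that 1000 placements can give, for every comparison except Kc167 H3K27me3 peaks against those of D17, where it was 0.002. That comparison had the lowest enrichment, 1.17 times random (24.6% of peaks against 21.0%). The test describes 2 lists and is no test between lines.

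Within each line, the question was which proteins and marks share sites. In D17, 307 of 380 ordered antibody pairs overlapped more often than random placements at an adjusted one-sided p under 0.05 and 52 less often; in Kc167 these were 76 and 11 of 90, and in S2 319 and 46 of 380. The pairs named here were chosen after their values were seen. Pho and its partner Sfmbt were tightly linked: 62.3% of D17 Sfmbt peaks held a Pho peak (22.7 times random, adjusted permutation p = 0.00126), as did 43.8% in S2 (15.2 times random, adjusted p = 0.00121). Pho peaks held a Spps peak in 51.1% of cases in D17, 85.5% in Kc167 and 68.6% in S2.

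Ph and Pc, which belong to the same complex, differed in the marks they overlapped. In D17, 59.5% of Ph peaks lay over H3K27ac (3.34 times random) and 13.9% over H3K27me3, a share that did not pass the test (1.02 times random, adjusted permutation p = 0.414 for excess). D17 Pc peaks lay over H3K27me3 in 66.5% of cases (4.51 times random) and over H3K27ac in 17.9% (0.918 times random, adjusted permutation p = 0.140 for deficit). S2 Pc peaks lay over H3K27me3 in 64.9% of cases and S2 Ph peaks in 18.6%. In Kc167, by contrast, 62.2% of Pc peaks and 66.3% of Ph peaks lay over H3K27ac. The Kc167 Pc list was longer, however (6298 peaks, against 2529 in D17 and 2387 in S2), and these shares were not taken at equal list lengths. H3K4me3 and H3K27me3 kept apart: 0.196% of D17 and 0.454% of S2 H3K4me3 peaks touched H3K27me3. With the merged regions of all of a line's lists as the background in place of whole chromosomes, the pairs below random numbered 8 in D17, 6 in Kc167 and 4 in S2.

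Sites where Ph, Pc, Psc and Pho peaks coincided were then defined as PcG sites, since these 4 antibodies have lists in all 3 lines. There were 485 sites in D17, 2068 in Kc167 and 573 in S2. Merged, they made 2318 places, of which 262 were sites in all 3 lines, 268 in 2 lines, 124 in D17 only, 103 in S2 only and 1561 in Kc167 only. Of the D17 sites, 291 were sites in S2 (share interval 55.5% to 64.4%) and 332 in Kc167 (68.5%, 64.1% to 72.6%). Kc167 sites were sites in D17 in 16.2% of cases and in S2 in 21.2%. All 6 shares lay 18.7 times or more above random placements (one-sided permutation p = 0.001, the smallest they can give).

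The number of sites depended on its definition. Requiring any 3 of the 4 proteins gave 728, 3494 and 1162 sites in D17, Kc167 and S2, and requiring peak centres within 500 bp gave 181, 1489 and 326. With the higher-scoring 50% of each list the numbers were 273, 590 and 280, and Kc167 sites were sites in D17 in 39.2% of cases and in S2 in 40.0%. When every list was shortened to the shortest of its antibody, Kc167 had 495 sites, D17 484 and S2 442, and these shares of Kc167 sites were 53.1% and 58.2%. With centres within 500 bp they were 4.30% and 10.2%.

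The sites held by most lists in each line were named by a rule fixed beforehand. In D17 they were a site at the PRC1 genes ph-d and ph-p (X 2121203 to 2126056, peaks in 19 of 20 lists, H3K27ac but no H3K27me3), a site at engrailed (2R 11527491 to 11530225, 19 lists, both marks) and one with no gene within 5 kb (3R 163845 to 168534, 18 lists, both marks). Kc167 sites with peaks in all 10 lists lay near tin and mod(mdg4) (3R 21376212 to 21379448), near CG8066 (3R 14568468 to 14569068) and near RYBP and CG13516 (2R 22670596 to 22671003), each with both marks. In S2 they lay on the Y chromosome (1020426 to 1027815, 19 lists), near dco and Sox100B (3R 31060231 to 31062771, 18 lists) and near ph-p (X 2134578 to 2138935, 17 lists), also with both marks. The rule itself favours sites with both marks, and peaks in all 10 Kc167 lists require them. Not all sites are strong: the Ph peak of the gene-free D17 site stood at the 12.1 percentile of folds in its list, against 99.0 for the site at engrailed. That D17 site lacked only GAF and H3K4me3 and the Y site only Sfmbt, so H3K27me3 and H3K36me3 peaks lay over each. Whether peaks of nearly every list at these 2 sites reflect PcG binding was not tested.

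The histone marks over these sites asked whether PcG proteins occur without the repressive mark. In D17, 316 of 485 sites (65.2%, interval 60.7% to 69.4%) had H3K27me3 only, 82 (16.9%, 13.7% to 20.5%) had H3K27ac only, 28 had both and 59 had neither. S2 had 308 of 573 sites with H3K27me3 only (53.8%, 49.6% to 57.9%) and 151 with H3K27ac only (26.4%, 22.8% to 30.2%). Kc167 was the other way round, with 399 of 2068 sites under H3K27me3 only (19.3%, 17.6% to 21.1%) and 1440 under H3K27ac only (69.6%, 67.6% to 71.6%). At the 262 places that were sites in every line the states were close, with H3K27me3 only at 74.0% in D17, 80.2% in Kc167 and 82.1% in S2, and 194 places carried H3K27me3 in all 3 lines.

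**Figure D2:**
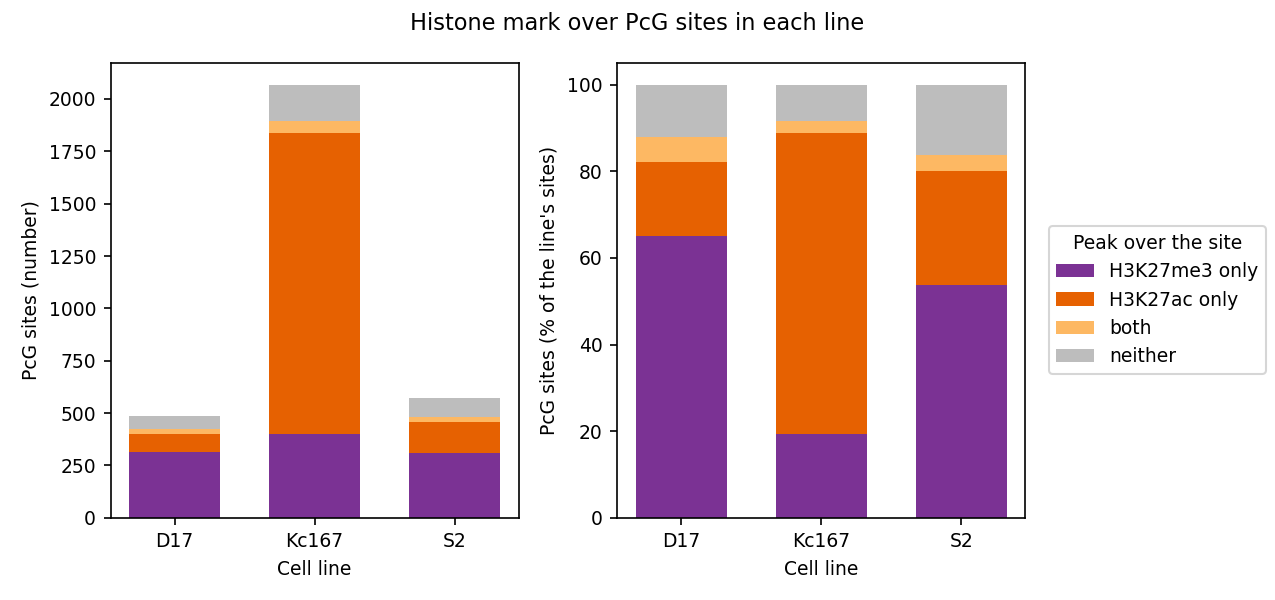
PcG sites of each cell line (x axis) as numbers (left) and as percent of the line's sites (right), with bar parts for the mark whose peak lies over the site. H3K27ac only makes up 69.6% of the 2068 Kc167 sites, 26.4% of the 573 S2 sites and 16.9% of the 485 D17 sites.

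H3K27ac-only sites had lower enrichment than H3K27me3-only sites of the same lists. The weakest of the Ph, Pc, Psc and Pho folds of a site had a median of 2.26 against 4.29 in D17, 1.84 against 4.14 in Kc167 and 1.98 against 6.04 in S2. The proteins differed: in D17 the median Ph folds were close (6.15 against 6.69), while those of Pc were 2.61 against 10.3. With the Ph, Pc, Psc and Pho lists shortened to the shortest of the antibody and the mark lists whole, a setting chosen after the data were seen, the H3K27ac-only share of Kc167 sites fell from 69.6% to 37.6% (33.3% to 42.0%), against 16.9% (13.7% to 20.6%) in D17 and 21.3% (17.5% to 25.4%) in S2. The H3K27me3-only share of Kc167 sites was then 50.5%.

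Some partners of the PcG sites differed with the mark. H3K4me3, found at active promoters, covered 1.27% of H3K27me3-only and 47.6% of H3K27ac-only sites in D17, and 2.60% and 58.9% in S2. Rad21 was at 45.5% of H3K27me3-only and 96.0% of H3K27ac-only sites in S2 (intervals 39.8% to 51.2% and 91.6% to 98.5%). Engrailed was at 33.2% and 63.4% in D17, and TrxN at 16.8% and 31.7% in D17 and at 53.6% and 76.8% in S2. Scm, which links PRC1 and PRC2, went the other way, at 98.4% of H3K27me3-only and 80.5% of H3K27ac-only sites in D17 and at 93.2% and 41.7% in S2. H2AK118ub1 also favoured H3K27me3-only sites, with 93.0% against 68.3% in D17, 45.4% against 34.3% in Kc167 and 49.0% against 16.6% in S2. Spps was at 93.9% or more of the sites of either kind in every line, and Sfmbt at 91.9% or more in D17 and S2. E(z) of PRC2 differed little, at 70.3% of H3K27me3-only and 74.4% of H3K27ac-only sites in D17 and 86.0% and 79.5% in S2. TrxC was at 53.2% and 56.1% in D17, 76.3% and 81.5% in S2, and 74.2% and 92.9% in Kc167. H3K4me2 lay over many sites of both kinds, 55.1% and 64.6% in D17 and 32.1% and 47.7% in S2.

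**Figure D3:**
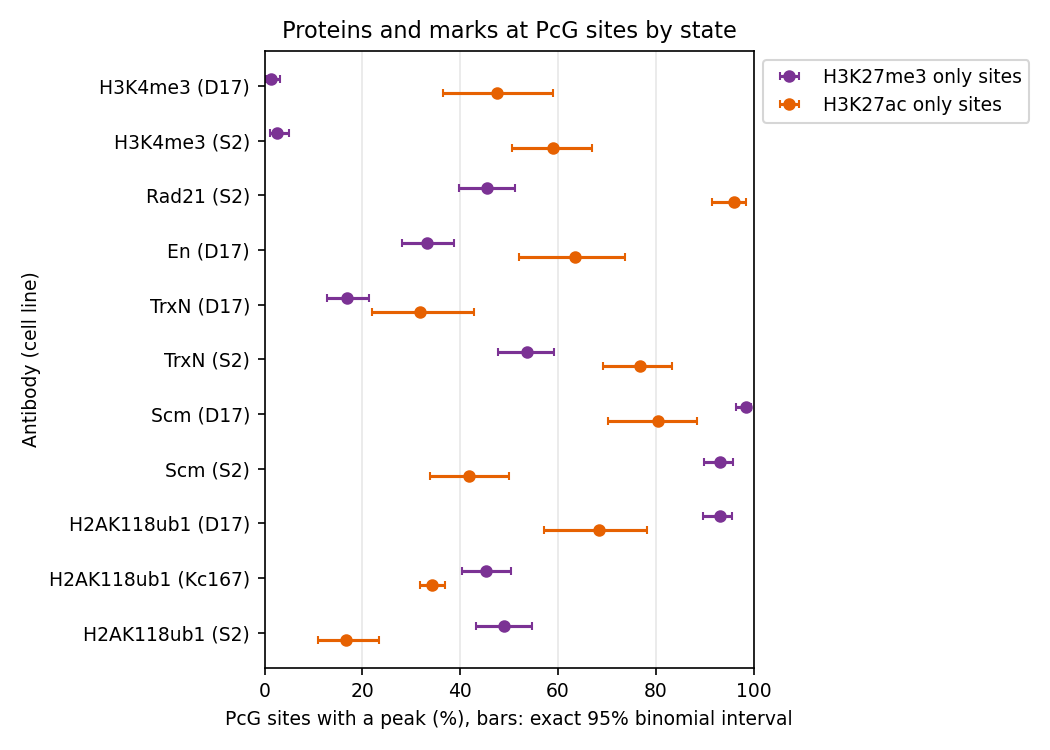
Percent of PcG sites with a peak (x axis) of selected antibodies, for H3K27me3-only and H3K27ac-only sites of a line. Bars are exact 95% binomial intervals. H3K4me3, Rad21, En and TrxN lie higher at H3K27ac-only sites, and Scm and H2AK118ub1 at H3K27me3-only sites.

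Sites that carried H3K27me3 only in one line and H3K27ac only in another asked whether PcG proteins stay when the mark differs. Of the 399 such Kc167 sites, 37 were H3K27ac only in D17, where a Ph peak lay over 30 (81.1%, 64.8% to 92.0%), a Spps peak over 32, a Psc peak over 25, a Pho peak over 23 and a Pc peak over 17 (45.9%, 29.5% to 63.1%). For comparison, the Kc167 sites that were H3K27me3 only in D17 too had Ph there in 84.0% and Pc in 93.4% of cases. Those with neither mark in D17 had Ph in 49.0% and Pc in 45.9%. Of the 308 S2 sites, 15 were H3K27ac only in D17, with Ph over 13 and Pc over 12. Kc167 sites were H3K27ac only in S2 at 20 places, with Ph over 17 and Pc over 11. In Kc167, 7 D17 and 8 S2 sites were H3K27ac only, all with Ph and Pc. In S2, 3 D17 sites were, with Ph over 2 of them and Pc over none. Genes within 2 kb, chosen after their values were seen, include chinmo, tio, croc, rpr, ct and inv (Kc167 to D17), Psc and 3 sites at zfh2 (S2 to D17), the GATA factor genes srp and pnr (Kc167 to S2) and toy and cnc (to Kc167 from D17 and S2). The number for Kc167 to D17 was 24 where a mark had to cover at least 50% of the site and 16 with the higher-scoring 50% of each list, and that for Kc167 to S2 was 12 with those lists. The numbers in Kc167 fell from 7 to 3 for D17 sites under either setting, and from 8 to 5 for S2 sites where a mark had to cover at least 50% of the site.

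Protein-coding genes with at least 50% of their body under H3K27me3 numbered 1065 in D17, 2148 in Kc167 and 2246 in S2, of 13935. The mark covered 17.6 Mb, 23.3 Mb and 26.2 Mb. In all, 3421 genes were covered in some line and 506 in all 3. D17 genes were covered in S2 in 72.8% of cases, whereas 34.5% of S2 genes were covered in D17, and 1410 of the S2 genes had 0 bp of H3K27me3 in D17. Kc167 and S2 shared 1182 genes. A limit applies to genes without the mark: peak numbers in each list run in genome order with gaps, so a peak may have been removed where a number is missing. The H3K27me3 lists skip numbers at 29 stretches (457 protein-coding genes) in D17, 15 (267 genes) in Kc167 and 24 (331 genes) in S2.

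The gene lists fixed beforehand showed where the mark lay. It covered all 8 homeotic genes in D17 and S2 and 6 in Kc167, where random lists of the same size and gene length held a median of 1. Segmentation genes were covered in 21 (D17), 24 (Kc167) and 24 (S2) of 29, with random medians of 2, 5 and 5; eve, odd, slp1, slp2, gsb and kni had 100% of the body covered in every line. Genes that pattern wings and legs were covered in 25, 29 and 30 of 35, including vg, Dll, nub and ara at 100% in every line. Retinal and head genes were covered in 8, 7 and 9 of 9, and neural and muscle genes in 20, 23 and 23 of 34, where ac, sc, l(1)sc, ase and vnd lie at a skipped number of the D17 list. For these 5 lists, at least 99.96% of 10000 random lists held fewer covered genes. Random members were drawn singly, while list members can be neighbours under the same peak, as inv and en are in Kc167 and S2. The percents treat such neighbours as independent.

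Blood cell genes, the type S2 and Kc167 are described as resembling, stood near random, with 3 (D17), 4 (Kc167) and 3 (S2) of 19 covered against random medians of 2, 3 and 4. An H3K27ac peak lay within 500 bp of an end of 11, 9 and 12 of them. With at least 80% of the body required, the S2 number was 1. Genes that encode PcG and trithorax group proteins were covered in 0, 3 and 3 of 29, those in Kc167 and S2 being Psc, Su(z)2 and jing. H3K27ac lay at an end of 24, 27 and 22 of them, and 99.2% of random lists in D17, 99.99% in Kc167 and 96.9% in S2 held fewer, the S2 value falling short of a two-sided threshold of 0.05. None of the 28 housekeeping genes was covered in any line; 27, 27 and 26 had H3K27ac at an end, and a PcG site lay within 5 kb of 0, 13 and 3.

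Members of the homeotic, segmentation and appendage lists that were covered in one line and not in another were named in full. Covered in S2 and not in D17 were 10 genes: bi (91.5% of the body against 14.6%), bab1 (78.7% against 0%), zfh2, bab2, inv, Wnt4, ap (92.8% against 13.6%), Wnt6, al and en. They include the wing selector apterous and the T-box gene bifid. Covered in D17 and not in S2 were pnr (91.7% against 0%) and run (100% against 0%). Kc167 covered 11 genes that D17 did not, namely bi, bab1, bab2, inv, ap, Wnt6, ptc, tsh, tio, en and gt, while D17 covered rn (92.9% against 4.7%), dpp (82.7% against 19.6%) and sob (100% against 0%) and Kc167 did not. S2 covered zfh2, rn, dpp, Wnt4, al and sob and Kc167 did not, and Kc167 alone of these 2 covered pnr, ptc, run and gt. Both run and gt lie on chromosome X, which held 6.57% of the H3K27me3 length in S2 against 11.9% in D17 and 16.4% in Kc167. The remaining cases touch a skipped peak number. Antp, Scr and ftz were at 93.7% or more in D17 and S2 and at 0% in Kc167, whose list skips 1 number between 3R 6818964 and 7105392, a stretch with 14 Kc167 PcG sites. The S2 values of 0% for tsh and tio, at 100% in Kc167, lie where the S2 list skips a number, 2L 21595043 to 22646301. These 5 values of 0% are therefore no evidence of absence.

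**Figure D4:**
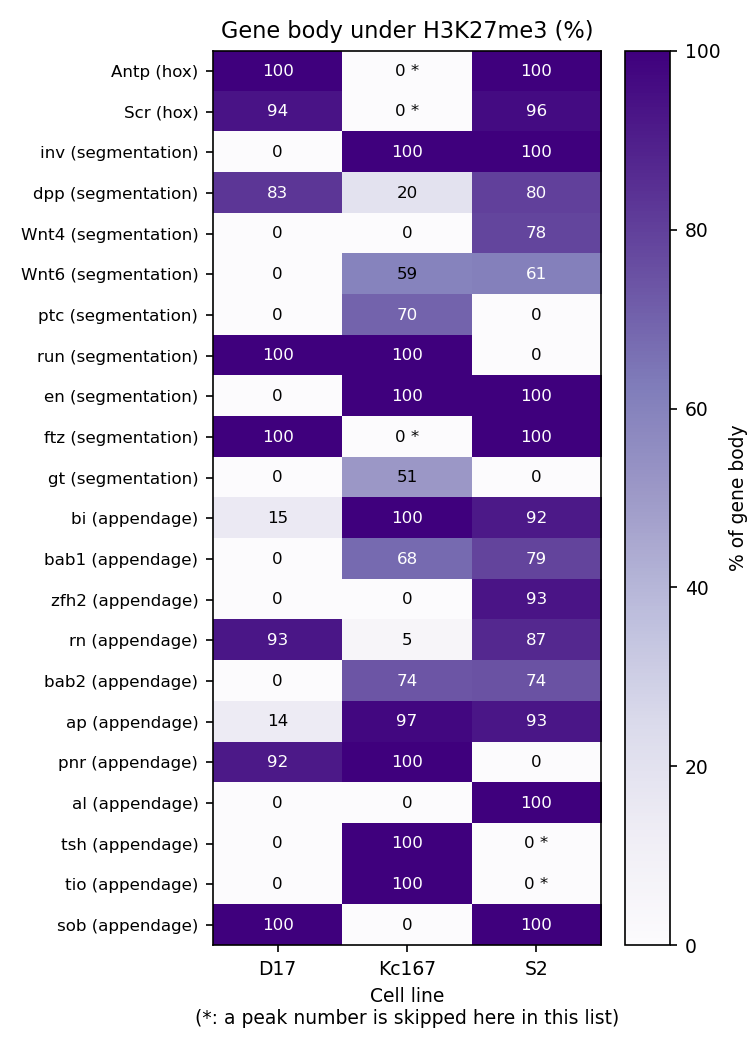
Percent of the gene body under H3K27me3 peaks (colour and printed value) for the list genes (y axis) whose coverage differs between cell lines (x axis); * marks a gene where the list skips a peak number. bi, bab1, bab2, inv, ap, Wnt6 and en are covered in both Kc167 and S2 and at 14.6% or less in D17.

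Beyond the lists, the longest covered genes with 0 bp in another line were named. D17 covered bru3 (260 kb), dpy (97.1 kb) and CG34353 (89.3 kb), each with 0 bp in both other lines, as well as ds (Kc167 at 0 bp), mgl and beat-VI (S2 at 0 bp). Kc167 covered Ptp61F, Ten-m, Sdc, Glut1 and br with 0 bp in D17, and Mur2B, Ten-m, Zasp52, Mnr and sbb with 0 bp in S2. Of the genes with 0 bp in S2, mgl, Mur2B and Mnr lie on chromosome X. S2 covered Ptp61F, tei, CG42342, Glut1 and dpr11 with 0 bp in D17, and tei, dpr11, Stacl and sns with 0 bp in Kc167, as well as Antp at the skipped number. Some of these peaks lay close to the lowest deposited fold of 1.5: the D17 fold was 1.57 for bru3 (63.2 percentile of its list), 1.51 for dpy (23.0) and 1.54 for CG34353 (48.9), and the S2 fold was 1.51 for tei (14.5). A value of 0 bp beside such a peak is weak evidence of a difference.

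The interval of invected and engrailed, neighbouring homeobox genes, was compared between lines as fixed beforehand. H3K27me3 covered 100% of inv (2R 11474465 to 11509695) and 100% of en (2R 11524006 to 11528210) in Kc167 and S2 and 0% of both in D17, and the D17 H3K27me3 list skips no number there. With 50 kb added on each side, the interval was covered to 36.4% in D17, 88.2% in Kc167 and 88.9% in S2; with 20 kb, the D17 value was 20.7%. In D17, 35 H3K27ac peaks lay in the interval and covered 68.4% of inv and 88.2% of en, against 0% of both genes in Kc167 and S2. H3K36me3 covered 23.4% of inv and 72.8% of en in D17 and 0% of both in Kc167 and S2, but the D17 peaks stood at the 0.0710 (inv) and 14.7 (en) percentiles of folds in their list. H2AK118ub1 covered 100% of both genes in D17, against 9.58% of inv and 0% of en in Kc167 and 23.9% and 41.9% in S2. It covered 75.4% of the interval in D17, 2.36% in Kc167 and 9.29% in S2. The D17 list of this mark was also the longest, at 39.6 Mb against 16.5 Mb in Kc167 and 15.5 Mb in S2.

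PcG proteins were present at both genes in every line. The site beside en had Ph, Pc, Psc, Pho and Spps peaks at the 96.2 percentile or above of folds in each line's lists. At the site in inv, the D17 Pc peak stood at the 86.7 percentile and the Pho peak at the 80.9 percentile of their lists, while Ph stood at 93.7 and Spps at 99.1. There, S2 had Pc at 98.7 and Pho at 93.3, and Kc167 had Pc at 99.3 and Pho at 97.7.

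**Figure D5:**
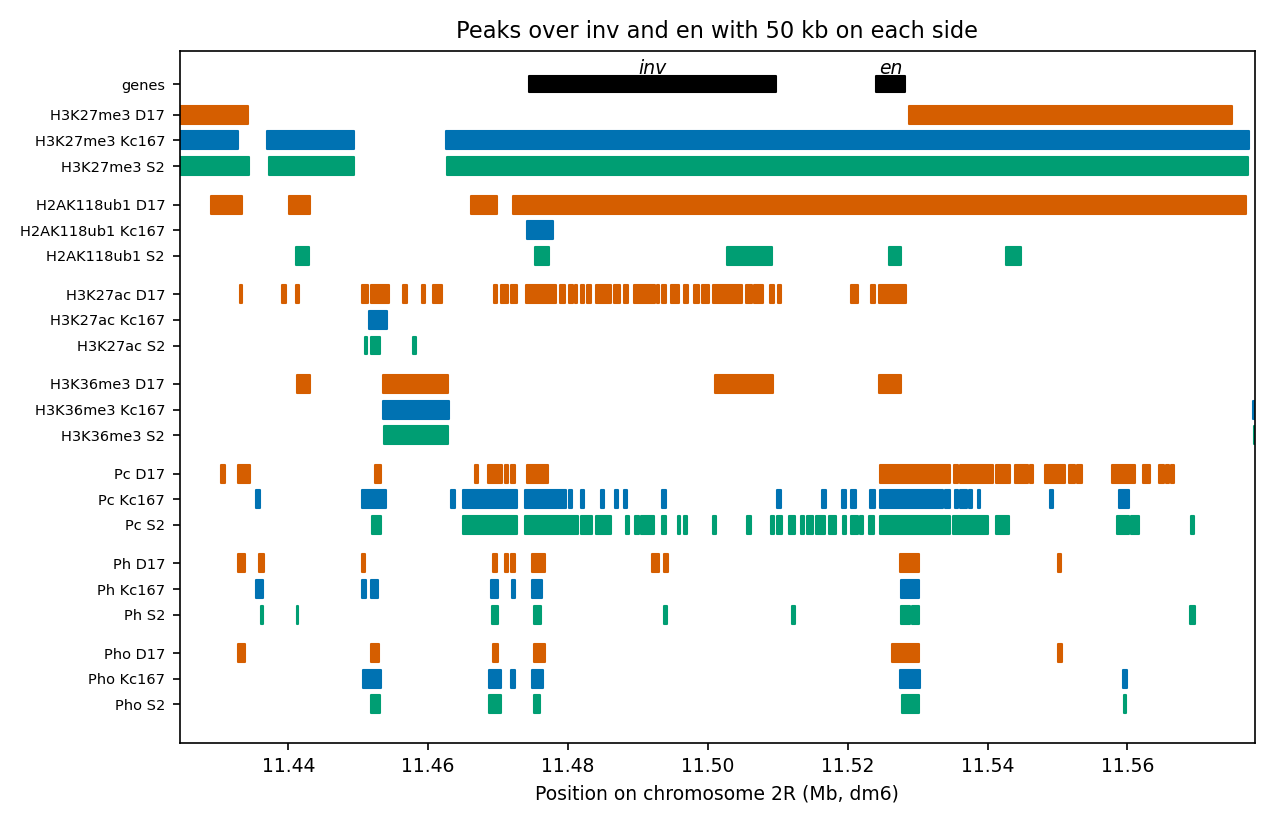
Peaks of selected antibodies (1 row per list) over inv and en with 50 kb on each side, by position on chromosome 2R in Mb. In D17, H3K27ac peaks cover 68.4% of inv and 88.2% of en and no H3K27me3 peak reaches either gene, while PcG protein peaks stand at both genes in all 3 lines.

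The share of H3K27me3 under the PRC1 mark differed between lines, while its enrichment over random was closer. H2AK118ub1 covered 39.6 Mb in D17, 16.5 Mb in Kc167 and 15.5 Mb in S2. It lay over 61.6% of the H3K27me3 length in D17 (30.6% at random), 21.6% in Kc167 (12.5% at random) and 29.6% in S2 (12.9% at random). Genes with at least 50% of the body under H2AK118ub1 numbered 3657, 1374 and 1576, and 2837 (77.6%), 842 (61.3%) and 700 (44.4%) of these had no H3K27me3 at all. H3K27me3 covered at least 50% of the body of only 7.64%, 15.4% and 16.1% of all protein-coding genes. The share of all genes without any H3K27me3 is not given here. H2AK118ub1 peaks held a PcG site in 5.94%, 43.2% and 6.35% of cases (1.95, 2.51 and 2.31 times random). With overlap required over at least 50% of the width of a peak, the D17 value was 0.746 times random, a setting that a broad peak can rarely meet over a narrow site.

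Both Trithorax antibodies marked promoters and PcG sites to different degrees. TrxN peaks lay over H3K4me3 in 84.4% (D17) and 76.8% (S2) of cases, TrxC peaks in 40.1% in each line. PcG sites held TrxN in 21.0% (D17) and 63.9% (S2) of cases and TrxC in 52.0% (D17), 88.7% (Kc167) and 79.4% (S2). Against random placements, TrxN stood at 5.39 (D17) and 12.3 (S2) times, and TrxC at 4.74 (D17), 8.91 (Kc167) and 24.9 (S2) times. The higher D17 share of TrxC was thus not a higher enrichment. TrxN peaks lay over H3K27me3 less often than placements over whole chromosomes (0.439 times random in D17 and 0.485 in S2). Even so, TrxN was at 16.8% (D17) and 53.6% (S2) of H3K27me3-only PcG sites. TrxC peaks lay over H3K27me3 more often than random in S2 (30.9% of peaks, 1.43 times) and less often in D17 (0.863 times) and Kc167 (0.742 times). With the higher-scoring 50% of each list the latter values turned to 1.07 and 1.23 times random. No value against merged regions is given here for Trithorax. TrxN over H3K4me2 in D17 (3.93 times random) was 1.08 times random, and no longer past the test, with overlap over at least 50% of the peak width.

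H3K36 methylation and H3K27me3 occupied separate chromatin. H3K36me3 length lay under H3K27me3 at 0.0658 times random in D17, 0.0110 times in Kc167 and 0.0222 times in S2. H3K36me2 did so at 0.0393 times random in D17 and 0.307 times in S2, where 6.41% of its length lay under H3K27me3. H3K36me2 length lay under H3K36me3 to 66.0% in D17 and 68.2% in S2.

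Engrailed, profiled in D17 alone, had 1586 peaks, of which 13.6% lay over PcG sites (21.4 times random), 53.5% over H3K27ac (3.38 times), 49.3% over GAF (9.64 times) and 18.5% over H3K27me3 (1.39 times). Of the D17 PcG sites, 41.0% held an Engrailed peak. Rad21, profiled in S2 alone, had 5673 peaks, of which 76.2% lay over H3K27ac and 66.8% over H3K4me3. Of the S2 PcG sites, 64.4% held a Rad21 peak, although 6.96% of Rad21 peaks lay over one. Rad21 peaks lay over H3K27me3 in 6.05% of cases (0.288 times random); with the merged regions of all S2 lists as the background this turned to 1.27 times. The 60 tests on marks, Trithorax, Engrailed and Rad21 had a two-sided p of 0.002 each, the smallest that 1000 placements can give, and 0.002 after adjustment.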

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

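The alternatives that leave out stretches at skipped peak numbers, that leave out X and Y, that shorten the Ph, Pc, Psc and Pho lists alone, or that use a peak over either gene end were chosen only after the results were seen. Across 143 results, 359 alternatives were run: 317 kept the result, 37 moved its value, 1 weakened it and 4 reversed it. For a tested result, kept means the same direction and side of the threshold, for a count within 1.5 times and for another share within its 95% interval. The tested shares of PcG sites that were sites in another line stayed above random while their values changed: Kc167 sites in D17 went from 16.2% to 53.1% with equal list lengths and to 4.30% with centres within 500 bp, and S2 sites in D17 from 51.3% to 14.7% with the latter. All 78 comparisons between lines stayed above random under all 4 alternatives run for them, and the numbers of H3K27me3 genes moved by less than 1.5 times under all 6 of theirs. No paired analysis was possible because the lists carry no values per replicate; for the same reason no replicate was left out. The factor motif alternatives (no genome sequence was used) and an H3K27me3 peak over the annotated start (no strand was given) were not run. Unknown depth limits any reading of a missing peak as absence.

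With the higher-scoring 50% of each list, the number of peaks was 113839 by construction, PcG sites numbered 273 (D17), 590 (Kc167) and 280 (S2), Kc167 antibody pairs below random 4, and Kc167 H3K27me3-only sites that were H3K27ac only numbered 16 in D17 and 12 in S2, and D17 sites H3K27ac only in Kc167 3. TrxC over H3K27me3 turned to 1.07 times random in D17 and 1.23 in Kc167. With that part of the H3K27me3 and H3K27ac lists, the H3K27ac-only share was 11.5% (D17), 56.1% (Kc167) and 21.5% (S2). A background of merged regions gave 8 (D17), 6 (Kc167) and 4 (S2) pairs below random and turned Rad21 over H3K27me3 to 1.27. Any 3 of the 4 proteins gave 728, 3494 and 1162 PcG sites, a looser definition; centres within 500 bp gave 181 (D17) and 326 (S2); equal list lengths gave 495 (Kc167), with fewer peaks. With the Ph, Pc, Psc and Pho lists alone shortened, H3K27ac-only shares were 37.6% (Kc167) and 21.3% (S2) and H3K27me3-only shares 50.5% (Kc167) and 59.95% (S2). Marks over at least 50% of the site gave H3K27ac-only shares of 11.8% (D17), 62.1% (Kc167) and 18.5% (S2) and 24 Kc167 sites H3K27ac only in D17, with 3 D17 and 5 S2 sites H3K27ac only in Kc167; marks within 2 kb gave 59.0% in Kc167. Ph within 1 kb was at 100% of S2 sites H3K27ac only in D17, a wider search. With 80% of the gene body, 1 blood cell gene was covered in S2. With overlap over 50% of the width, TrxN over H3K4me2 in D17 was 1.08 and not past the test, and D17 H2AK118ub1 over PcG sites turned to 0.746, a setting that wide peaks rarely meet at narrow sites. With 20 kb flanks, inv-en coverage was 20.7% for H3K27me3 in D17, 3.87% for H2AK118ub1 in Kc167, and 0% (Kc167) and 0.458% (S2) for H3K27ac. Except where the construction is given, the cause was not tested.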

Other observations

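The tests of the number of Kc167 PcG sites at equal list lengths, of their H3K27ac-only share with whole mark lists, of peaks left out of the D17 H3K27me3 list, and of X folds in all 19 lists were chosen only after the results were seen. Genes covered by H3K27me3 in S2 and Kc167 with 0 bp in D17 numbered 646, 4 of them at a skipped number of the D17 list. In D17 most still carried the PRC1 mark: H2AK118ub1 lay over at least 50% of the body of 413 (63.9%), as it did for 411 of the 506 genes covered in all 3 lines (81.2%) and for 26.2% of all protein-coding genes. Active marks on them in D17 were rarer than on all protein-coding genes and more frequent than on those 506. An H3K27ac peak lay on 131 (20.3%, interval 17.2% to 23.6%) against 54.0% of all genes and 13.4% (10.6% to 16.7%) of the 506, H3K36me3 on 150 (23.2%) against 57.4% and 8.70%, and H3K4me3 on 41 (6.35%) against 47.5% and 0.395%. A Ph peak lay on 67 (10.4%), against 14.7% of all genes and 27.9% of the 506.

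The 1561 places that were PcG sites in Kc167 only lay at active chromatin in the other lines too. H3K27ac lay over 1325 of them (84.9%) in Kc167, 1202 in D17 and 1191 (76.3%) in S2, H3K4me3 over 69.6% in D17 and 67.5% in S2, and Rad21 over 76.2% in S2. A Ph peak was present at 729 (46.7%) in D17 and 859 in S2, and an end of a protein-coding gene lay within 500 bp of 68.0%. The 507 Kc167 sites shared with D17 or S2 had H3K27me3 in 61.5% of cases and a gene end in 48.5%.

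Kc167 had more PcG sites than the other lines, most of them over H3K27ac and not H3K27me3. Longer lists may account for the number and for the majority: with the Ph, Pc, Psc and Pho lists at equal lengths Kc167 had 495 sites, against 484 in D17 and 442 in S2, and the H3K27ac-only share fell from 69.6% to 37.6%. The lengths of these lists do not account for a share above that of the other lines, which with whole mark lists was 37.6% (33.3% to 42.0%) in Kc167, 16.9% (13.7% to 20.6%) in D17 and 21.3% (17.5% to 25.4%) in S2; shortening the mark lists too decides nothing, because the lines lost unequal parts of them. Weak peaks at active chromatin were not settled: the weakest of the 4 folds at H3K27ac-only sites had a median of 1.84 (quartiles 1.67 and 2.08) in Kc167, under the bound of 3 set for it, but also of 2.26 in D17 and 1.98 in S2, so the bound does not single out Kc167. A difference between the cell lines remains open and untested.

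D17 lacked H3K27me3 at genes that S2 and Kc167 cover, inv and en among them. A fold limit of 1.5 in the deposited lists was not excluded. Of the length of the 405 S2 peaks with the highest folds, 34.6% had no D17 mark, against 78.6% for the 407 lowest. The 34.6% lay above the bound set against the limit. But those 405 peaks start just above a fold of 1.64, and D17 folds reach 2.44 against 3.28 in S2. The mark could therefore lie under the limit in D17 even there. The S2 peak over inv and en stood at the 98.0 percentile of folds, and D17 had 20 H3K27ac peaks on inv and 1 on en, which argues against that limit there. Peaks removed after numbering account for little of the missing mark, since 0.982% of the 15.1 Mb of S2 length without D17 mark lay where the D17 list skips a number. The cell lines' different origins stay open as a biological explanation that was not tested.

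Chromosome X held 6.57% of the H3K27me3 length in S2, against 11.9% in D17 and 16.4% in Kc167, and less of other lists as well: 6.24% for H2AK118ub1 (11.9% and 17.8%), 9.47% for Pc (15.7% and 19.4%), 15.7% for Ph (21.3% and 22.7%) and 15.8% for H3K36me3 (18.3% and 18.4%), but 19.5% for H3K27ac (19.2% and 20.4%) and 8.51% for TrxC (4.18% and 21.4%). Peaks removed from the S2 list after numbering are not the source, as 0% of the 2.68 Mb of Kc167 X length without S2 mark lay where that list skips a number. Peaks left out before numbering would leave no skipped number and were not tested. Fewer X copies in S2 that lower folds on the X remain a candidate explanation that cannot be told apart from a difference between the lines. The fold ratios below lay on both sides of 1, and no input coverage or replicate spread was used here. The ratio of X to autosome median folds in S2 relative to D17 was 0.919 for H3K4me3 and 0.923 for H3K36me3, between the bounds set for either reading. It was 1.09 for GAF, above both, with a 95% interval from resampled peaks of 0.875 to 1.37. Over all peaks of the 19 lists of both lines, the interval lay above 1 in 6, Ph (1.29) and Pc (1.12) among them. It lay below 1 in 4, H3K4me3 and H3K36me3 among them. Over peaks found in both lines the interval lay above 1 in 2 lists, H3K27ac (1.09) and TrxC (1.31), and below 1 in 6. The ratio itself was above 1 in 5 of the 19 lists there, with Ph at 1.005, Pc at 0.918 and GAF at 0.913. For H3K27me3 it was 1.01 (0.992 to 1.02) over all peaks and 0.985 (0.946 to 1.04) over peaks found in both lines. Its median folds lay close to the lowest deposited fold of 1.5 (1.59 on X and 1.57 on autosomes in S2, 1.55 and 1.54 in D17). In any list, X peaks lowered beneath that limit would be absent. Ratios near or above 1 therefore cannot count against lowered folds on the X.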
